A study of Homo sapiens with 3 samples.

How the data were processed

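The series holds RNA-seq of 3 libraries of MCF7 cells, an oestrogen receptor-positive human breast cancer line. One library came from cells transfected with a control siRNA, one from cells transfected with USP1 siRNA-1 and one from cells transfected with USP1 siRNA-2. Groups were taken from the sample labels, giving 1 control library and 2 knockdown libraries. Each siRNA has 1 library, so the 2 knockdown libraries differ in both the siRNA and the culture, and p-values measure only the spread between these libraries. Counts of the 2 knockdown libraries differed by more than sampling noise (chi-square divided by its degrees of freedom 24.5), so they are not 1 library deposited under both labels.

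Per the labels' protocols, total RNA was extracted with TRIZOL and fragmented cDNA was end-repaired, tailed, ligated to adapters and amplified by PCR. Per the submitters' processing notes, TopHat2 2.0.9 and HTSeq were used with the genome build hg19. The gene annotation, the mapping options and the strand setting are not given in the sources used here. The authors deposited raw read counts per gene and FPKM values per gene in 1 table, with gene symbols, Ensembl gene identifiers and positions. The deposited FPKM values are the count divided by gene length and by the library's total count on genes. The gene length they imply agreed between libraries within a ratio of 1.00008 over 13501 genes. FPKM was used only to obtain gene length, and all tests used the deposited counts. The table had 31103 entries. Of these, 16 had blank values and were left out, which left 31087. In 29 entries a spreadsheet program had turned the gene name into a date, and 28 of these names were restored from their Ensembl identifiers. Gene names and the GC content of transcripts came from GENCODE v29 of build GRCh38, and no coordinate was taken from that build. A GC value was found for 94.9% of genes.

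Total counts were 11640035 in the control library, 13154667 with siRNA-1 and 12103880 with siRNA-2. A count of 0 allows a level of up to 0.258 CPM in the control library (3 counts of the total), 0.228 CPM with siRNA-1 and 0.248 CPM with siRNA-2. Ratios of a siRNA library to the control library carry exact Clopper-Pearson 95% intervals. The libraries have no molecular identifiers, so these intervals and limits cover counting error only.

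The design was fixed before the data were examined. The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization and filterByExpr (minimum count 10), which left 15475 genes. The knockdown was compared with the control, and genes were called at a Benjamini-Hochberg adjusted p of 0.05. With 1 residual degree of freedom, the spread comes from the difference between the 2 siRNA libraries, and the lone control library is assumed to vary like them. With 30.7 prior degrees of freedom, the spread used for a gene is mostly pooled over genes. It is only in small part that gene's own difference between the siRNAs. A size rule with no test was applied to the 11304 genes with a mean of at least 50 counts. It asked for at least a 2-fold difference from the control in the same direction with both siRNAs, on TMM-normalized log2 CPM with a prior count of 2. The same rule compared siRNA-1 with siRNA-2. Both siRNAs share the control library, so 100 simulations of unchanged groups sharing 1 control were made. Their spread was the trend over abundance seen between the siRNA libraries, with no spread particular to a gene and no shift particular to a library. They gave the overlap and correlation that arise with no effect under that spread.

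The 27 gene lists covered the USP1 complex and its substrates, Fanconi anaemia and homologous recombination, inhibitors of DNA binding, oestrogen receptor targets, DNA replication, mitosis, p53 targets, interferon, NF-kB, the unfolded protein and integrated stress response, heat shock, cholesterol synthesis, hypoxia and glycolysis, Wnt targets, TGF-beta and YAP targets, mesenchymal, epithelial and basal markers, histones, apoptosis, autophagy and lysosome, ribosomal proteins, mitochondrially encoded genes, RNA interference, and markers of fibroblasts, leukocytes and endothelium. They held 595 members, of which 572 were in the table. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists. With an estimated correlation camera uses the 1 residual degree of freedom left by these libraries, so hardly any list can pass. Not passing there does not show that correlation between genes accounts for a list. The p-values of list members were in addition adjusted by Benjamini-Hochberg over their list alone. That adjustment was not part of the fixed design and has no correction across the lists, so it is weaker than the one over all genes. The median log2 fold of each list was also placed among 10000 random lists of the same size matched on mean expression. Random lists draw each gene separately, so they do not vary together as the members of a list can. A list whose members vary together can reach an extreme percentile whenever single libraries differ, so a percentile is a description and no test.

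Named genes followed a rule: USP1; the 12 highest and 12 lowest genes under the size rule, ranked by the smaller of the 2 log2 folds; up to 4 members per list with the largest mean log2 fold; and the 5 highest and 5 lowest genes for siRNA-1 against siRNA-2. Genes named outside this rule are said to be chosen after their values were seen. Log2 folds for single siRNAs use the prior count, and pooled log2 folds are the fitted values of edgeR. Their SE is the absolute log2 fold divided by the square root of the F statistic. It therefore rests mostly on the spread pooled over genes, not on replicates.

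Other settings, also fixed before the data were examined, were DESeq2 size factors, library size without a composition factor, DESeq2 1.42.0, the legacy and robust forms of the quasi-likelihood fit, limma-trend, other filters, thresholds and prior counts, and leaving out each siRNA library. Removal of a trend on GC content and gene length, and removal of mitochondrially encoded genes, were added after the data were seen. On simulated counts of the 15475 genes with 200 changed genes, in 10 runs, the test recovered 15.7% of genes changed 2-fold and 81.9% of genes changed 4-fold, with a mean of 5.1 false calls per run. These counts followed the trend of spread over abundance, with no spread particular to a gene and no shift between libraries. Recovery and false calls may therefore be better than in the real data.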

Results

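RNA-seq libraries were made from MCF7 cells transfected with a control siRNA or with 1 of 2 siRNAs against USP1. USP1 is a deubiquitinase that removes ubiquitin from the DNA repair proteins FANCD2 and PCNA. The comparison asked which genes change expression when USP1 is knocked down. There was 1 control library, 1 library with siRNA-1 and 1 with siRNA-2, with 11640035, 13154667 and 12103880 counts on genes. The share of counts on mitochondrially encoded genes was 5.02% in the control library, 4.65% with siRNA-1 and 4.36% with siRNA-2. Ribosomal protein genes took 9.10%, 10.1% and 10.5% of counts. The summed level of 470 genes that this cell type should not express (olfactory receptor and keratin-associated protein genes) was 86.0 CPM in the control library, 57.5 CPM with siRNA-1 and 62.5 CPM with siRNA-2.

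USP1 (ENSG00000162607, hg19 chromosome 1, 62901968 to 62917475) was lower with both siRNAs. Its TMM-normalized level was 65.6 CPM in the control library, 14.5 CPM with siRNA-1 and 23.2 CPM with siRNA-2, from 765, 186 and 286 counts. The level with siRNA-1 was 0.221 of the control (95% Clopper-Pearson interval 0.187 to 0.260). With siRNA-2 it was 0.354 of the control (0.308 to 0.406). The fitted log2 fold of the knockdown was −1.80 ± 0.35 (SE, n = 1 control and 2 knockdown libraries), with an adjusted p of 0.0184 by the edgeR quasi-likelihood test. The adjusted p was 0.501 with library size as the only normalization and 0.740 with no filter on low counts, at nearly the same fold. It was 0.189 after a trend on GC content and gene length was removed, an alternative added after the data were seen.

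In the comparison of the knockdown libraries with the control library, 46 of 15475 genes tested were called, 15 higher and 31 lower than in the control library. Of these, 38 passed the 2-fold size rule with each siRNA. All 46 had the same sign with both, which the test and the shared control library largely fix in advance. With siRNA-2 taken as the single library instead, 46 genes were called as well. The genes called higher had a median GC content of 46.8% and a median length of 8950 bp, those called lower 57.4% and 4093 bp, and all tested genes 50.3% and 5002 bp. After a trend on GC content and length was removed, only CHAC1 of the 46 was still called. The folds stayed close to the main fit (median ratio 0.971, lowest 0.815; median SE 0.374 against 0.377), while the prior degrees of freedom went from 30.7 to 13.3. The largest fall among the genes named by the rule was in CHAC1 (hg19 chromosome 15, 41245160 to 41248710), which encodes an enzyme that degrades glutathione. CHAC1 went from 23.7 CPM in the control library to 1.40 CPM with siRNA-1 and 1.30 CPM with siRNA-2, a log2 fold of −4.12 ± 0.52 (SE, adjusted p = 8.70e-05). The keratin genes KRT8 and KRT18 of simple epithelia and the transcription factor gene XBP1 fell by 1.67, 1.71 and 1.67 on the log2 scale. Among the higher genes the smallest adjusted p was that of SULF1 (hg19 chromosome 8, 70378859 to 70573150), which encodes an extracellular sulfatase of heparan sulfate. It stood at 6.77 CPM in the control library, 31.4 CPM with siRNA-1 and 69.9 CPM with siRNA-2. Its log2 fold was 2.90 ± 0.47 (SE, adjusted p = 0.00199).

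Of the 12 genes named as lowest with both siRNAs, 10 were called. Besides CHAC1 these included the cation exporter gene SLC47A1 (log2 fold −2.78 ± 0.56), ULBP1, a ligand of the immune receptor NKG2D (−2.78 ± 0.57), and INHBE, an inhibin subunit (−2.69 ± 0.55; −2.10 with siRNA-1 and −3.43 with siRNA-2). PGF, a growth factor of the VEGF family, was at −2.38 ± 0.54 (−1.74 with siRNA-1 and −3.32 with siRNA-2), and SOCS3, an inhibitor of cytokine signalling, at −2.03 ± 0.38. ATP1A3, a sodium pump subunit, BAI2, S100A4 and SUSD2 fell by 1.90, 1.90, 1.82 and 1.80. The potassium channel gene KCNK15 (log2 fold −1.95, adjusted p = 0.0751) and HAP1 (−2.07, adjusted p = 0.0988) did not pass the edgeR test. Leukocyte markers, which these cells should lack, summed to 12.5 CPM in the control library, 8.97 CPM with siRNA-1 and 4.96 CPM with siRNA-2. Most of this sum was the lysosomal gene CD68, with 101 of 146 counts in the control library, 88 of 118 with siRNA-1 and 35 of 60 with siRNA-2, while LYZ (0, 4 and 5 counts) and CD3E (1, 4 and 2 counts), named after their values were seen, went the other way.

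Of the 12 genes named as highest with both siRNAs, 5 were called. These were FAM5B (log2 fold 3.74 ± 0.87), TIMP3, a metalloproteinase inhibitor (2.91 ± 0.65; 1.82 with siRNA-1 and 3.42 with siRNA-2), SULF1, the arrestin-domain gene ARRDC3 (2.12 ± 0.45) and G3BP2, which encodes a stress granule protein (1.76 ± 0.31). FAM5B rested on 0.429 CPM in the control library. The other 7 had adjusted p-values between 0.0751 for ZNF616 and 0.293 for SEMA3E by edgeR. NELL2, MAPK10, CDK14, AC005682.5 and REL had log2 folds of 2.48, 2.49, 2.28, 1.82 and 1.80 and did not pass.

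**Figure D1:**
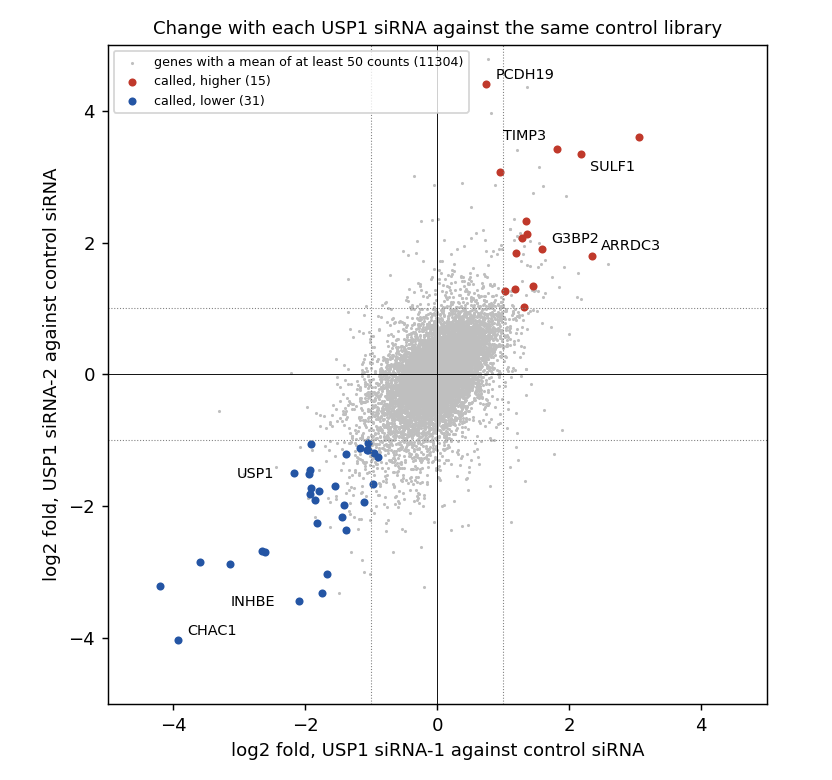
Each point is a gene, placed by its log2 fold with USP1 siRNA-1 (horizontal axis) and with USP1 siRNA-2 (vertical axis) against the same control library; grey points are the 11304 genes with a mean of at least 50 counts, and dotted lines mark 2-fold. The 15 genes called higher (red) and the 31 called lower (blue) have the same sign with both siRNAs, with CHAC1 near −4 on both axes and PCDH19 at 0.75 and 4.40.

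The number of called genes depended on the fit. In 8 refits with another tool, normalization or filter, 2 called no gene (library size only, no filter) and the others called 13 to 134. Of the 46 genes called in the main test, 20 passed in only 2 of the 8 refits and 9 in 3. The 20 include PGF, ATP1A3, BAI2, FAM5B, BAG3, CLDN4, STC2, CELSR2 and PCDH19. The same 11 genes passed in all 6 refits that called any gene. The lower ones were CHAC1, KRT18, KRT8, KRT19, XBP1, ALS2CL, SOCS3, S100A4 and USP1, and the higher ones were G3BP2 and NOLC1. ALS2CL (log2 fold −1.62 ± 0.27), a gene for an ALS2-like protein, and the nucleolar protein gene NOLC1 (1.40 ± 0.27) lie outside the naming rule and were chosen after their values were seen.

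**Figure D2:**
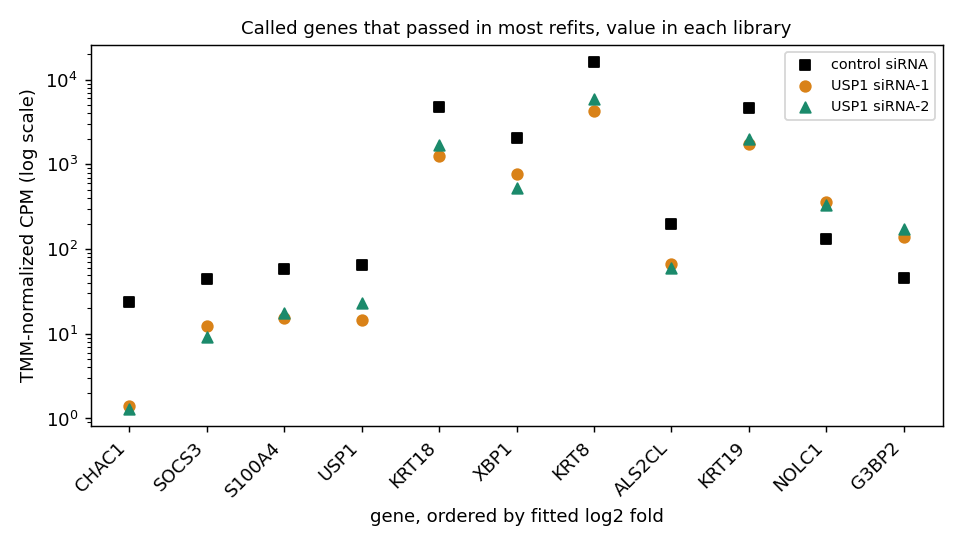
TMM-normalized CPM (log axis) of the 11 genes called in 6 of the 8 refits, with one point per library. CHAC1, SOCS3, S100A4, USP1, KRT18, XBP1, KRT8, ALS2CL and KRT19 lie lower in both siRNA libraries than in the control library, and NOLC1 and G3BP2 lie higher.

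Genes of the unfolded protein and integrated stress response were lower as a list. Of 28 members tested, 3 fell (CHAC1, XBP1 and ASNS), none rose and 25 did not pass. Adjusted over the list alone, 4 fell, the fourth being DDIT4 (log2 fold −0.97 ± 0.27; −0.70 with siRNA-1 and −1.30 with siRNA-2), named after its values were seen. ASNS, which encodes asparagine synthetase, went from 232 CPM in the control library to 107 CPM with siRNA-1 and 60.4 CPM with siRNA-2 (log2 fold −1.47 ± 0.29, adjusted p = 0.0199 by edgeR). The cystine transporter gene SLC7A11 had log2 folds of −0.42 with siRNA-1 and −2.09 with siRNA-2 and did not pass. Log2 folds were below 0 with both siRNAs for 21 members, and the list median was −0.18 with siRNA-1 and −0.74 with siRNA-2. The median over both siRNAs lay at percentile 0 of 10000 random lists matched on expression, the measure behind every list percentile given here. Such percentiles treat members as varying separately, so an extreme one is no test of the knockdown. The stress response list passed camera at the preset correlation (adjusted p = 0.000281). It did not pass on 1 residual degree of freedom (adjusted p = 0.915 with an estimated correlation), where hardly any list can. Some lists also passed at the preset correlation with either siRNA library taken as the single one. Passing camera is therefore not particular to the comparison with the control library, for this list or for the others.

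Epithelial junction and keratin genes included 4 falls among 18 members. KRT8 (hg19 chromosome 12, 53290977 to 53343666) went from 16194 CPM in the control library to 4272 CPM with siRNA-1 and 5902 CPM with siRNA-2. KRT18 (hg19 chromosome 12, 53342655 to 53346685) went from 4816 CPM to 1254 CPM and 1699 CPM, and KRT19 from 4584 CPM to 1761 CPM and 1995 CPM. CLDN4, a tight junction claudin, was at −1.10 ± 0.24 (adjusted p = 0.0412 by edgeR). Adjusted over the list alone, 5 fell, the fifth being CLDN3 (−0.73 ± 0.27), named after its values were seen. The list passed camera as lower at the preset correlation (adjusted p = 0.0422). It did not pass on 1 residual degree of freedom (adjusted p = 0.915 with an estimated correlation). After the GC and length trend was removed its camera adjusted p was 0.0558, and with no filter it was 0.139, at medians of −0.17 and −0.15 against −0.19 in the main setting (percentile 0.17). The main median was −0.09 with siRNA-1 and −0.46 with siRNA-2. The median difference of the members between the siRNAs was only 0.10, at percentile 62.21 of matched random lists. Of the 4 called members, KRT8, KRT18 and KRT19 were lower with siRNA-1, and CLDN4 was slightly lower with siRNA-2 (−1.06 and −1.14). The KRT8 and KRT18 loci overlap by 1012 bp and both genes have pseudogenes, so the split of counts between them is uncertain.

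Of 33 oestrogen receptor targets and luminal regulators, 4 fell (XBP1, SLC7A5, STC2 and CELSR2), none rose and 29 did not pass. XBP1 is also a member of the stress response list and is counted as a fall in both. The amino acid transporter gene SLC7A5 had a log2 fold of −1.10 ± 0.23, the hormone gene STC2 −1.28 ± 0.29 (−0.97 with siRNA-1 and −1.66 with siRNA-2) and the cadherin-like gene CELSR2 −1.07 ± 0.25. These 3 were named after their values were seen. Adjusted over the list alone, 9 fell and 3 rose, the latter AREG, TFF3 and ELOVL2, of which TFF3 and ELOVL2 were named after their values were seen. AREG, a ligand of the EGF receptor, had a log2 fold of 1.75 ± 0.52 (2.12 with siRNA-1 and 1.17 with siRNA-2), and EGR3 one of −1.66 ± 0.44 (−1.26 and −2.16), both short of the threshold over all genes. KRT13 had a fitted log2 fold of −3.74 ± 0.99 from 1.71 CPM in the control library and also fell short. The list did not pass camera (adjusted p = 0.258), and its median lay at percentile 0.11.

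DNA replication and E2F target genes were higher as a list, with no single member past the test among 38. Log2 folds were above 0 with both siRNAs for 23 members, and the list median was 0.11 with siRNA-1 and 0.26 with siRNA-2. The fitted log2 folds of CCNE1, ORC1, CDC6 and CHAF1A were 0.67, 0.58, 0.51 and 0.51. The 38 ribosomal protein genes likewise had no member past the test, and 33 lay above 0 with both siRNAs, with medians of 0.15 and 0.15. RPL11 and RPL28 had log2 folds of 0.59 and 0.51, and their processed pseudogenes make these counts uncertain. The camera adjusted p was 0.0373 for replication genes and 0.0397 for ribosomal proteins (adjusted p = 0.915 with an estimated correlation for both). The replication median lay at percentile 99.91 of matched random lists and the ribosomal protein median at 90.39, within their usual range. For ribosomal proteins the camera adjusted p was 0.0575 when at least 1 CPM was asked in all libraries.

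Among mitotic genes none of 40 passed, 23 lay below 0 with both siRNAs, and the list did not pass camera (adjusted p = 0.0719), with its median of −0.22 at percentile 0. The median was −0.03 with siRNA-1 and −0.36 with siRNA-2, so it rested on the siRNA-2 library. It passed when at least 1 CPM was asked in all libraries (adjusted p = 0.0279) and after the GC and length trend was removed (adjusted p = 0.0261). In the main setting it had an adjusted p = 0.915 with an estimated correlation. NEK2, a mitotic kinase gene, had a log2 fold of −0.87 ± 0.37, and NUF2, PTTG1 and CDC25C had log2 folds of −0.58, −0.53 and −0.49. Of 11 genes of the USP1 complex and its substrates pathway, a list that leaves out USP1 itself, none passed (camera adjusted p = 0.877, percentile 3.65). FANCD2, PCNA, ATAD5 and FANCL had log2 folds of −0.25, 0.30, 0.38 and −0.28. Of 26 Fanconi anaemia and homologous recombination genes none passed, and 16 lay above 0 with both siRNAs (camera adjusted p = 0.101, percentile 99.79). BRCA2 and XRCC2 had log2 folds of 0.94 ± 0.35 and 1.01 ± 0.44.

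The heat shock list held 2 falls among 13 members, in the co-chaperone gene BAG3 (log2 fold −1.14 ± 0.25, adjusted p = 0.0351 by edgeR) and the small heat shock protein gene HSPB1 (−1.07 ± 0.24, adjusted p = 0.0412). HSPA8 and HSPD1, at 0.63 and 0.60, did not pass, and 9 members lay above 0 with both siRNAs. The list median of 0.41 lay at percentile 99.99 of matched random lists, and camera gave an adjusted p of 0.258. In the mesenchymal and invasion list 1 of 13 fell, S100A4, which encodes a calcium-binding protein, from 57.9 CPM to 15.3 CPM with siRNA-1 and 17.5 CPM with siRNA-2. Adjusted over the list alone the integrin gene ITGA5 fell as well (−1.62 ± 0.44; −1.32 with siRNA-1 and −1.94 with siRNA-2), and camera gave an adjusted p of 0.0685 (percentile 1.28). Of 10 basal and stem-like markers none passed over all genes. SOX2, a pluripotency transcription factor gene, passed when adjusted over the list alone, at 3.60 CPM in the control library, 8.49 CPM with siRNA-1 and 39.8 CPM with siRNA-2. The list's camera direction was lower (adjusted p = 0.0719, percentile 8), with ITGA6 and PROM1 at −1.64 and −1.64. It passed once the GC and length trend was removed (adjusted p = 0.0490). In the main setting it had an adjusted p = 0.915 with an estimated correlation.

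Of 31 p53 targets none passed over all genes and 1 rose when adjusted over the list alone, PLK2, at 13.1 CPM in the control library, 38.1 CPM with siRNA-1 and 40.8 CPM with siRNA-2 (camera adjusted p = 0.0929, percentile 95.5). Of 21 apoptosis regulators none passed over all genes and PMAIP1, a BH3-only gene, fell when adjusted over the list alone (log2 fold −1.43 ± 0.38, −0.97 with siRNA-1 and −2.09 with siRNA-2; camera adjusted p = 0.808, percentile 14.75). BCL2 and CASP7 had log2 folds of −0.86 and 1.07. No member passed, over all genes or over the list alone, among 29 interferon-stimulated genes, 11 NF-kB genes, 4 inhibitors of DNA binding, 23 cholesterol synthesis genes, 27 hypoxia and glycolysis genes, 15 Wnt targets, 14 TGF-beta and YAP targets, 12 histone genes, 23 autophagy and lysosome genes, 13 mitochondrially encoded genes and 13 RNA interference genes. Camera gave adjusted p-values of 0.350, 0.509, 0.808, 0.170, 0.808, 0.258, 0.261, 0.864, 0.170, 0.808 and 0.227 for these lists in the same order. Their medians lay at percentiles 50.87, 6.08, 1.23, 97.61, 3.72, 2.65, 0.84, 55.53, 0.05, 1.46 and 82.21. For hypoxia and glycolysis the list median was −0.08 while its mean (0.01) and the camera direction were positive.

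Markers of other cell types were measured as a check of the libraries. Beside the leukocyte markers, endothelial markers summed to 9.54 CPM in the control library, 3.72 CPM with siRNA-1 and 6.11 CPM with siRNA-2. Both lists passed camera as lower (adjusted p = 0.0218 for each) on 3 and 4 tested members, with none past the test singly (adjusted p = 0.915 with an estimated correlation for both). The leukocyte median lay at percentile 13.14 of random lists of like abundance and the endothelial median at 1.35. With no filter the adjusted p was 0.273 for leukocyte and 0.0653 for endothelial markers. VWF and PTPRC had 3.43 and 1.29 CPM in the control library. Fibroblast markers summed to 61.9, 49.0 and 47.0 CPM and did not pass (camera adjusted p = 0.658, percentile 39.39).

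**Figure D3:**
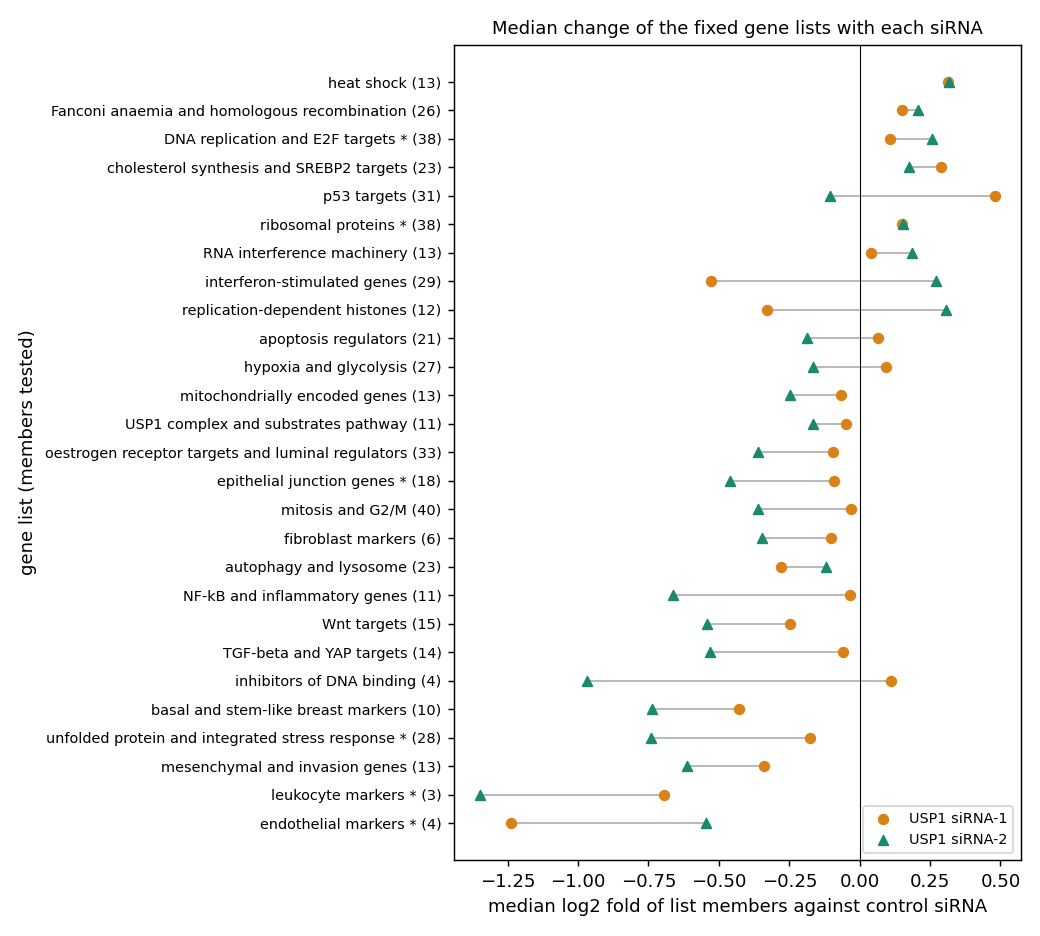
Median log2 fold of the members of each fixed gene list against the control library, with USP1 siRNA-1 as circles and siRNA-2 as triangles; the number of members tested is in brackets and an asterisk marks lists with a camera adjusted p under 0.05. The stress response list lies at −0.18 and −0.74, and the p53 target list at 0.48 and −0.11.

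Taken one at a time, siRNA-1 put 150 of 11304 genes at least 2-fold above the control library and 289 at least 2-fold below. With siRNA-2 these numbers were 278 and 450. In the same direction with both there were 59 higher and 116 lower genes, and 8 genes were 2-fold in opposite directions. Unchanged groups sharing 1 control gave on average 81.0 higher (62 to 107 in 100 simulations) and 42.6 lower (28 to 65), and independent lists of these sizes would share 3.69 higher and 11.5 lower genes. Across genes, which are not independent replicates, the log2 folds of the 2 siRNAs had a Pearson r of 0.532 against a simulated mean of 0.501 (0.483 to 0.520), and a covariance of 0.133 against 0.121. Spearman's rho was 0.492 against 0.479 (0.460 to 0.493), and 66.8% of genes had the same sign with both siRNAs against 66.7% (65.5 to 67.6), both within the simulated range. With siRNA-2 taken as the single library, the same comparison gave an r of 0.626 and 277 genes past the 2-fold rule in the same direction, against 0.532 and 175 with the control as the single library. The higher count thus lay below every simulation and the lower count above every one. The simulations already share 1 control, so noise in a shared control is part of their counts. Since the higher count lay below all of them, this model of no effect does not describe these data well. The lower count above it is therefore no measure of an effect. With 1 control library, a shift particular to that library cannot be told apart from an effect of the knockdown.

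The siRNA libraries also differed from each other, with 273 genes at least 2-fold higher with siRNA-1 than with siRNA-2 and 259 at least 2-fold lower. These 532 genes compare with 439 for siRNA-1 against the control library and 728 for siRNA-2 against it. By this count the siRNA-1 library was nearer to the control library than to the siRNA-2 library. Each side is 1 library, so these differences have no replicate check. The highest with siRNA-1 was AKR1C2, a steroid-metabolizing reductase gene, at 79.5 CPM in the control library, 173 CPM with siRNA-1 and 16.7 CPM with siRNA-2. The transporter gene ABCC3 stood at 41.6, 36.3 and 4.30 CPM in the same order, and GDF15, a stress-induced cytokine gene, at 233, 323 and 47.5 CPM. NGFR and SERPINA3 were 2.98 and 2.95 higher on the log2 scale with siRNA-1. The largest values in the other direction were for C11orf92, at 0.343, 0.701 and 13.7 CPM, and the protocadherin gene PCDH19, at 5.23, 8.88 and 114 CPM. UNC5C stood at 1.03, 2.88 and 24.3 CPM, CDH18 at 0.772, 1.48 and 14.4 CPM, and EHF at 1.54, 1.17 and 13.6 CPM. PCDH19 was the only one of these 10 genes called in the pooled test (adjusted p = 0.0351 by edgeR), with log2 folds of 0.75 with siRNA-1 and 4.40 with siRNA-2.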

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

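The removal of a GC content and length trend and of mitochondrially encoded genes were chosen after the data were seen; the other alternatives were planned. No called result reversed. Among lists that did not pass, the fibroblast list went from lower (median −0.24) to higher (0.58) with at least 1 CPM in all libraries, and with no filter the camera direction of the USP1 complex and histone lists turned from lower to higher while their medians stayed below 0. With the GC and length trend removed, the hypoxia and apoptosis medians turned from below to above 0 (0.04 and 0.01, neither list past camera). The count of 46 called genes (15 higher, 31 lower) was 13 (3 and 10) with DESeq2 size factors, 18 (9 and 9) with DESeq2, 21 (4 and 17) with a robust prior, 16 (3 and 13) with at least 1 CPM in all libraries, 127 (52 and 75) with limma-trend and 134 (54 and 80) with the legacy fit. By edgeR it was 0 (0 higher, 0 lower) with library size only and 0 (0 and 0) with no filter, with 914 and 971 genes at an unadjusted p under 0.05, against 1062 in the main test. It was 1 (0 higher, 1 lower) with the GC and length trend removed. USP1 kept its direction throughout, with log2 folds of −1.80 with library size only, −1.76 with no filter and −1.82 with the trend removed, where it no longer passed; adjusted p ranged from 0.000268 to 0.740. The median absolute log2 fold of the 46 genes was 1.80 in the main test, 1.80 with library size only, 1.77 with no filter and 1.68 with the trend removed, with median SE of 0.377, 0.365, 0.355 and 0.374. The prior degrees of freedom behind the test were 30.7, 8.12, 2.17 and 13.3 in the same order, and 368 in the legacy fit.

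The 175 genes past the 2-fold rule with both siRNAs (59 higher, 116 lower) became 435 (135 and 300) with a mean count minimum of 10, 65 (26 and 39) with a minimum of 200 and 813 (379 and 434) with a 1.5-fold threshold. For siRNA-1 against siRNA-2, the 532 genes became 1198, 215 and 2016 in the same order. With 1 siRNA library left out the rule rests on the other siRNA alone, by construction a wider rule, and gave 439 to 728 genes (150 to 278 higher, 289 to 450 lower). Of 27 lists, 6 passed camera, 3 with no filter and 0 with an estimated correlation, where the smallest unadjusted p was 0.196. That camera p was for ribosomal proteins, whose estimated correlation of −0.0014 lay below the preset 0.01. At the preset correlation their unadjusted camera p was 0.00735. With 1 residual degree of freedom, the setting with an estimated correlation cannot decide whether correlation between genes accounts for the lists. Without 1 siRNA library, the called genes and the lists have no test, because 1 library against 1 leaves no residual degrees of freedom. No paired analysis was possible because there is 1 control library. Alternatives planned for normalized values were not run, since counts were deposited. The prior degrees of freedom were not varied alone, and the robust prior called 21 genes at the same median of 30.7. Beyond the construction of the rules, the cause of these changes was not tested. At this depth and design, most 2-fold changes would be missed: 15.7% were recovered in simulated data.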

Other observations

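The tests of other splits, of the control library alone and of the amino acid response part, the siRNA-against-siRNA list percentiles and the removal of the GC trend were chosen after the results were seen. Several gene lists stood apart between the 2 siRNA libraries, as a description of 1 library against 1. Members that vary together can reach extreme percentiles with any difference between 2 libraries. The median p53 target was 0.50 higher on the log2 scale with siRNA-1 than with siRNA-2, at the 100th percentile of 10000 random lists matched on expression. CDKN1A, the cell cycle inhibitor gene, stood at 383 CPM in the control library, 534 CPM with siRNA-1 and 144 CPM with siRNA-2, and was named after its values were seen. Interferon-stimulated genes showed the opposite order, with a median difference of −0.64 (percentile 0), and a list median of −0.53 with siRNA-1 and 0.27 with siRNA-2. In this list IFI6 stood at 6.52, 4.52 and 24.3 CPM and IFIT1 at 1.97, 2.57 and 7.31 CPM, also named after their values were seen, and 1 of the 29 members tested, SAMD9L, had a mean under 10 counts.

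The inhibitor of DNA binding genes ID1, ID2 and ID3, whose proteins USP1 is known to stabilize, were at 0.441, 0.383 and 0.591 of the control with siRNA-2 and at 0.929, 0.790 and 1.26 of the control with siRNA-1. The fourth member, ID4, went the other way, at 1.68 of the control with siRNA-2 and 3.41 with siRNA-1. The median of the list was 1.06 higher with siRNA-1 than with siRNA-2 (percentile 100). NF-kB genes and TGF-beta and YAP targets were higher with siRNA-1 by medians of 0.64 and 0.55 (percentiles 99.96 and 99.98). None of these lists, nor those of p53 targets and interferon-stimulated genes, passed camera for the knockdown against the control. Mitotic genes, which did not pass camera either, were higher with siRNA-1 by a median of 0.26 (percentile 99.93). The stress response list (median 0.54 higher with siRNA-1, percentile 100) and the DNA replication list (median difference −0.20, percentile 0.05) also stood apart between the siRNAs, and these did pass camera for the knockdown at the preset correlation (adjusted p = 0.915 with an estimated correlation for both).

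With each library taken in turn as the single one, 2 of 3 splits gave at least 46 called genes. The real split gave 46, siRNA-2 against the others also 46 and siRNA-1 against the others 0, and 3 splits are too few for a share under 0.05. Legacy calls were 134 in the real split, 163 with siRNA-2 single and 0 with siRNA-1 single, genes past the 2-fold rule 175, 277 and 83, and lists passing camera 6, 9 and 5. Of the 46 genes, 2 were also called with siRNA-2 as the single library. This overlap does not decide whether that library stands apart. A gene that differs between the control and both siRNAs has, by construction, a wide spread in the other splits. Over 11304 genes the SD of the log2 difference was 0.454 between control and siRNA-1 and 0.493 between the siRNAs. Between control and siRNA-2 it was 0.550 (Pearson r of log2 CPM 0.966, 0.960 and 0.948 in the same order). By these distances siRNA-2 lay farthest from the other libraries, with 1 library each and no replicate check. After a trend on GC content and length was removed, 1 of the 46 was still called. The median ratio of their log2 folds after to before was 0.971 (lowest 0.815), and their median SE went from 0.377 to 0.374. The calls ended as the prior degrees of freedom went from 30.7 to 13.3. The count of calls alone therefore cannot tell a GC trend and an effect of the knockdown apart. Folds kept at 0.815 or more of their earlier size argue against that trend as their main source, for these 46 genes.

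The stress response list remained lower after the GC and length trend was removed, with a median of −0.39 and a camera adjusted p of 0.000444 at the preset correlation, which argues against that trend as the whole cause. Before the trend was removed the list had an adjusted p = 0.915 with an estimated correlation; background RNA in the control library is argued against, since the median fall of its members in CPM was 119 times the level of a silent gene. For 21 of 28 members the control library was above both siRNA libraries; with 1 control library, an unusual control and an effect of the knockdown cannot be told apart.

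An untested hypothesis for the stress response list is that the fall lies mainly in the ATF4 and amino acid response genes rather than in the chaperone genes of the endoplasmic reticulum. The median was −0.63 in the former (18 genes) and −0.20 in the latter (10 genes), a larger gap than in 99.39% of 10000 random partitions of the list. This partition test decides nothing, because the parts were drawn up after the values were seen. With siRNA-1 the medians were −0.19 and −0.16, and with siRNA-2 −1.03 and −0.46, so the gap rests on the siRNA-2 library.

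Genes of low abundance had higher values in the control library. For genes with a mean of 1 to 5 counts, the summed level with siRNA-1 was 0.725 of the control and with siRNA-2 0.806, and for genes of 200 to 1000 counts these ratios were 1.02 and 1.01. Silent genes, which a breast cell should not express, had a ratio of 0.668 (95% interval 0.607 to 0.736) with siRNA-1 and 0.726 (0.660 to 0.799) with siRNA-2. These ratios are what more background RNA or DNA in the control library would give. Silent genes are themselves of low abundance, at 0.183 CPM per gene in the control library. Their ratios therefore cannot tell background apart from another cause that raises low counts in that library. No biological explanation was tested.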
